A study of Mus musculus with 2 samples.

How the data were processed

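PAR-CLIP libraries were made from testis lysates of 10-week-old ICR mice given 4-thiouridine, with an ALKBH5 antibody or nonspecific IgG, per the labels' protocols. RNA was crosslinked at 365 nm, digested with RNase T1 after the immunoprecipitation, and made into libraries with a small RNA kit. There were 2 libraries, 1 per group. Reads were aligned with BWA 0.5.8 to the mouse build NCBIM37, per the submitters' processing notes. How clusters were called, how reads with several matching places were assigned, and which test gave the p-values are not given in the sources used here.

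The deposited table gives raw read counts of both libraries per cluster, not scaled. Clusters are named by strand. The log2 fold change in the authors' table is log2 of the IP count over the IgG count, with 0.5 in place of 0, which held for all 2964 clusters within 1e-06. A second column, the scaled log2 fold change of the authors, adds 1 constant per strand, -0.09 on the minus and 0.10 on the plus strand. The deposited z-score of each cluster is a score of the authors' test, and the deposited p-value and q-value columns come from that test on 1 library per group. The listed p-values in the authors' deposited table reach 0.000988, under the threshold of 0.001 that the header names. No cluster overlapped another on the same strand.

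The library totals were recovered from the deposited z-scores. A normal approximation for the log ratio of 2 binomial counts given their mean, with totals per strand as unknowns, gave all z-scores back with a largest difference of 9.16e-08. The totals were 21830938 minus and 9837907 plus reads for the IP, and 20467640 and 10563705 for IgG. From the quotient of deposited p-values and q-values, 68943 clusters had been tested, 39013 on the minus and 29930 on the plus strand. Of the 9277 at or below the largest listed p of each strand, 2964 (32.0%) are listed, and the other 6313 were not analysed here.

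Counts were scaled to the total of each library over both strands. The ratio of IP to IgG was taken per cluster where IgG reads were listed. The count of clusters at a ratio of at least 2 used a pseudocount of 1 and at least 10 reads in both libraries together, a minimum that removed no cluster. Exact binomial (Clopper-Pearson) 95% intervals of the IP share of the reads were turned into intervals of the ratio. Wilson 95% intervals were used for shares of clusters. The Wilson intervals treat clusters as independent draws, although the list was selected by p and holds repeated clusters, so they can be too narrow. Where IgG was listed as 0, the IP count was set against 3 reads per cluster and the fold is given as a lower bound. This bound concerns the IgG count only and leaves out counting error. No p-value was computed between the conditions. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used. On simulated counts of 2563 clusters for the IP and IgG comparison, 95.9% of intervals held the simulated ratio. Clusters simulated at ratios of 2, 4 and 8 came back at medians of 1.99, 3.94 and 8.00. The simulation drew Poisson counts, applied no p threshold and added no PCR copies. Its coverage therefore need not hold for the listed clusters.

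Most named clusters followed a rule set before the data were examined. It took the 15 highest ratios, the 10 with the most IP reads, the 5 lowest ratios, and up to 4 members of each gene list. The rule also left out entries with no gene name, which was dropped because no cluster had one. Named afterwards were the mitochondrial clusters at 244 and 1024 and the Y cluster at 328067. So were clusters with at least 1000 IP reads and a ratio of at least 4. The rule, the pseudocounts, minimums, ratio thresholds, median scaling, read weighting, the upper part of the clusters by reads and the removal of the mitochondrial genome were chosen before the data were examined. Scaling per strand, zeros set to 3, the removal of clusters at IgG 0, of short clusters and of clusters at the repeated spacing, dense loci and all later tests were chosen afterwards. Gene lists, annotation classes and their alternatives could not be run, because no annotation of NCBIM37 was used here, with the exception of the mitochondrial genome, which the table names as a chromosome. The gene table at hand is of another build, GRCm38.p6, and none of its coordinates was used.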

Results

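RNA recovered from mouse testis with an antibody to ALKBH5, a nuclear enzyme that removes methyl groups from RNA, was compared with RNA recovered by nonspecific IgG. The assay was PAR-CLIP, in which the photoreactive nucleoside 4-thiouridine is built into RNA and crosslinked to bound protein with light, here of 365 nm. The mice were 10 weeks old and of the outbred ICR strain. There were 2 libraries, 1 from the ALKBH5 immunoprecipitation (IP) and 1 from IgG, so no value has a replicate and no test between the conditions was possible. The table lists 2964 clusters, which are stretches of 1 strand covered by reads, with the read count of each library. The library totals behind the table, as recovered from its z-scores, were 31668845 reads for the IP and 31031344 for IgG. Whether they count all aligned reads or only reads in the tested clusters is not known. Shares of a library given here are shares of these totals. The listed clusters held 55.2% of the IP reads and 46.3% of the IgG reads. All positions are in the mouse build NCBIM37. Genes, exons and introns were not assigned, because no annotation of this build was used here.

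The comparison of the IP with IgG asks which RNA regions the ALKBH5 antibody recovered beyond nonspecific binding. Most listed clusters were higher in the IP by less than 2-fold or rested on few reads. Clusters with many reads were only slightly higher in the IP. The clusters with the highest ratios were mostly short, or lay in a 5.07 kb stretch of chromosome 2 and near the start of chromosome 9. Several groups of low-read clusters lay together over longer stretches; the p threshold of the table lists a cluster of few IP reads only where IgG reads were few or listed as 0.

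Of the 2964 clusters, 2117 had IgG reads and 847 (28.6%, Wilson 95% interval 27.0 to 30.2%) had an IgG count listed as 0. Among the 2117 clusters the median ratio of IP to IgG, scaled to the library totals, was 1.79, with quartiles of 1.40 and 2.57. The exact binomial 95% interval of the ratio lay above 1 in 2083 of them, held 1 in 25 and lay below 1 in 9. It lay above 2 in 266 clusters. With a pseudocount of 1 added to both counts, 1690 of the 2964 clusters (57.0%, Wilson interval 55.2 to 58.8%) reached a ratio of 2, and 1025 reached a ratio of 4. Without the clusters at IgG 0, 843 clusters reached a ratio of 2 with the same pseudocount. These intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules, and they compare 2 libraries, not the conditions. The table lists only clusters under its own p threshold and higher in the IP by the authors' scaling, so clusters with no difference or with more IgG reads were not analysed here.

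The ratio fell with the number of reads. In the 277 clusters with 11 to under 50 IP reads and with IgG reads, the median ratio was 3.64. It was 2.26 in the 650 such clusters with 50 to under 200 IP reads and 1.55 in the 684 with 200 to under 1000. In the 338 clusters with 1000 to under 10000 IP reads it was 1.36, and in the 168 with 10000 or more it was 1.23. A cluster with few reads needed a higher ratio to pass the table's p threshold, so this trend was partly set by the listing. Of the 847 clusters at IgG 0, 810 had under 50 IP reads.

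**Figure D1:**
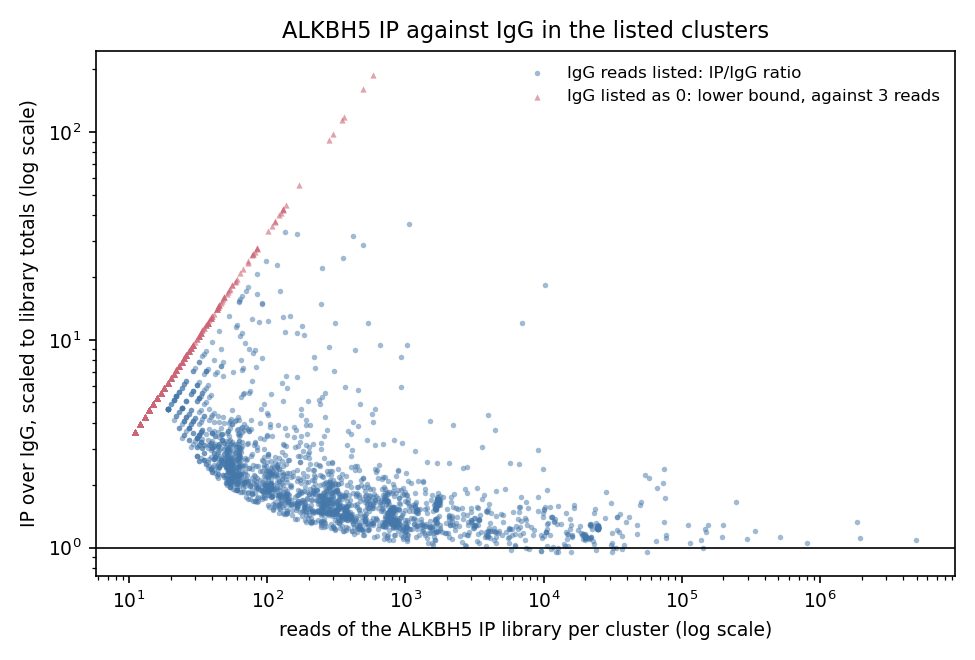
Each point is 1 of the 2964 listed clusters, with the reads of the ALKBH5 IP library on the horizontal log axis and the ratio of IP to IgG, scaled to library totals, on the vertical log axis. Circles are the 2117 clusters with IgG reads, and triangles are lower bounds for the 847 clusters with IgG listed as 0, set against 3 reads; the circles approach a ratio of 1 as reads rise.

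**Figure D2:**
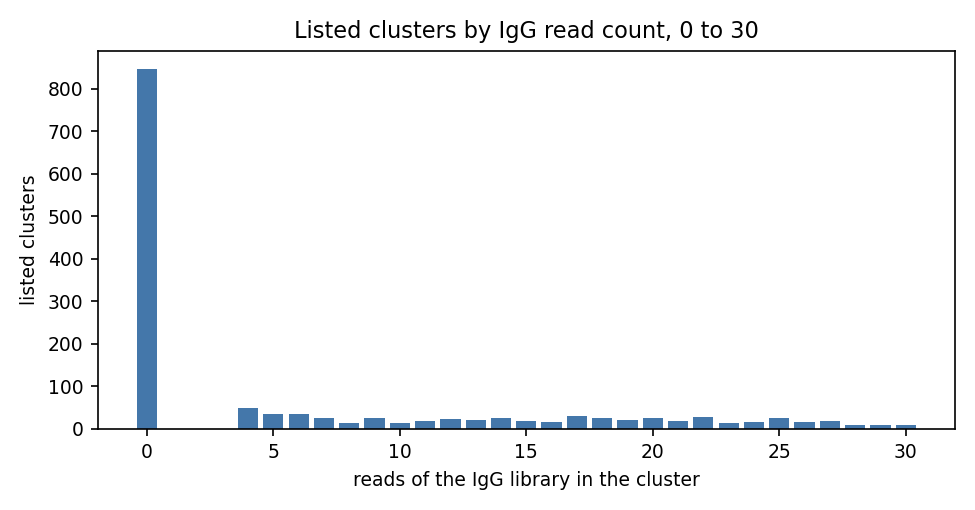
Bars give the number of listed clusters on the vertical axis for each IgG read count from 0 to 30 on the horizontal axis. There were 847 clusters at 0, none from 1 to 3 and 50 at 4.

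The 10 clusters with the most IP reads held 35.8% of the IP library and 31.2% of the IgG library, a ratio of 1.15 between their shares. The largest lay on the minus strand of chromosome 16 at 57391222 to 57391790, with 4931650 IP and 4411757 IgG reads and a ratio of 1.10 (exact binomial interval 1.09 to 1.10). A 25-base cluster on the minus strand of chromosome 5 at 23907910 to 23907934 followed, with 1934346 and 1703114 reads and a ratio of 1.11. The cluster on the minus strand of chromosome 18 at 73693060 to 73693197 had 1862759 IP and 1373071 IgG reads, a ratio of 1.33 (1.33 to 1.33). These 3 clusters alone held 27.6% of the IP library and 24.1% of the IgG library. A 3136-base cluster on the plus strand of chromosome 17, at 39982641 to 39985776, had 803849 and 747871 reads and a ratio of 1.05. On the minus strand of chromosome 9, the cluster at 56071380 to 56071766 had a ratio of 1.13. On the plus strand, the clusters at 94343132 to 94343161 of chromosome 16 and at 115301978 to 115302046 of chromosome 5 had ratios of 1.20 and 1.10. The highest ratio of the 10 was 1.66 (1.65 to 1.67), at 69733218 to 69733248 on the plus strand of chromosome 17, with 246434 and 145561 reads. The last of the 10 were minus clusters at 25695377 to 25695404 of chromosome 15 and 131178604 to 131178633 of chromosome 2, with ratios of 1.28 and 1.12. The direction of all 10 turned when the libraries were scaled to the median ratio of the listed clusters in place of the library totals, a shift of 0.84 on the log2 scale that places the middle of the clusters with IgG reads at a ratio of 1 by construction.

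The 15 clusters with the highest ratios all had an IgG count of 0. Against 3 IgG reads they were at least 36.9-fold to at least 189-fold higher in the IP, without counting error. The lower limits of their exact binomial 95% intervals, with IgG taken as 0, ran from 29.5 to 153. The highest was a 20-base cluster on the plus strand of chromosome 3, at 30936282 to 30936301, with 578 IP reads. Of the 15, 7 were 20 bases or shorter, among them also an 18-base plus cluster on chromosome 4 at 82646171 to 82646188 (361 reads, at least 118-fold) and a 17-base minus cluster on chromosome 11 at 71748091 to 71748107 (281 reads, at least 91.8-fold). Of the other 8, 5 lay in 1 stretch of chromosome 2 and 2 near the start of chromosome 9. On chromosome 2 the minus cluster at 98507191 to 98507460 had 493 reads and the plus cluster at 98507066 to 98507191 had 350. The remaining cluster was on the minus strand of chromosome 12 at 3109893 to 3110049, with 130 reads and an at least 42.5-fold difference. Whether reads of these 15 clusters also match other places in the genome was not checked.

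Clusters with many reads and a high ratio were few. Chosen after the values were seen, 6 clusters had at least 1000 IP reads and a ratio of at least 4, and all were 17 to 26 bases long. The one with the most reads lay on the minus strand of chromosome 8 at 77517630 to 77517648, with 10195 IP and 545 IgG reads and a ratio of 18.3 (16.8 to 20.02). A plus cluster on chromosome 1 at 99558184 to 99558200 had 6927 and 561 reads, a ratio of 12.1 (11.1 to 13.2). The highest ratio measured with IgG reads was 36.1 (25.003 to 54.2), on the minus strand of chromosome 12 at 104553646 to 104553666, with 1069 and 29 reads. On chromosome 2 the minus clusters at 74493610 to 74493635 and at 174469802 to 174469822 had ratios of 9.47 (7.75 to 11.7) and 4.09 (3.64 to 4.60). The minus cluster on chromosome 3 at 151213823 to 151213843 had a ratio of 4.37 (4.06 to 4.70). For clusters this short, other matching places of their reads were not checked either.

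The 5 lowest ratios ran from 0.949 to 0.958, all on the plus strand. The lowest was on chromosome 3 at 61963215 to 61963294, with 56170 IP and 57997 IgG reads and an interval of 0.938 to 0.960. The others lay on chromosome 17 at 78535907, chromosome 15 at 47371532, chromosome X at 100868015 and chromosome 12 at 70782705. In the authors' deposited table each strand is scaled by its own constant. There the same 5 clusters have positive scaled log2 fold changes of 0.06 to 0.07, so their direction depended on the scaling. Compared with the totals of both strands, that scaling raises plus ratios and lowers minus ratios. Since the list holds only clusters higher in the IP by it, only plus clusters could have a ratio below 1.

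The composition of the listed clusters was described by strand, length and place. These clusters held 55.2% of the IP reads and also 46.3% of the IgG reads. Their shares therefore describe the list and not only RNA bound by ALKBH5. The clusters were split about evenly between the strands, with 1513 minus (51.0%, Wilson interval 49.2 to 52.8%) and 1451 plus. The minus clusters held 77.4% of the listed IP reads. Ratios of summed reads, scaled to the totals of both strands, were 1.19 on each strand, sums in which the 3 largest clusters held 49.97% of the listed IP reads. Scaled to each strand's own totals they were 1.14 on the minus and 1.30 on the plus strand. The median ratio of clusters with IgG reads was 1.73 on the minus and 1.90 on the plus strand. Short clusters were the most common: 1635 (55.2%, 53.4 to 56.9%) were 14 to 20 bases long, and they held 6.24% of the listed IP reads with a ratio of summed reads of 1.36. The 234 clusters of 100 bases or longer held 56.0% of the IP reads, with a ratio of 1.15. Of the 264 clusters of 50 to 99 bases, 66.3% (60.4 to 71.7%) had an IgG count of 0, against 14.4% (11.9 to 17.4%) of the 624 clusters of 21 to 30 bases. Read depth moved with length here, with median IP reads of 16 and 280. Among clusters with under 50 IP reads the shares were 86.9% (81.5 to 90.9%) of 198 and 64.7% (56.2 to 72.3%) of 133, still with median IP reads of 13 and 20. Chromosome 16 held 31.8% of the listed IP reads, with 4931650 of its 5552605 reads in 1 cluster. Chromosomes 5, 18 and 17 held 13.9%, 13.2% and 6.99%.

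Clusters were grouped into dense loci, defined after the values were seen as at least 5 clusters with gaps of at most 20 kb. There were 21 such loci with 295 clusters. Their clusters had an IgG count of 0 in 58.6% (52.95 to 64.1%) of cases, against 25.3% (23.6 to 26.9%) of the 2669 other clusters. Median IP reads were 26 in the dense loci and 111 elsewhere. Among clusters with under 50 IP reads the shares were 81.5% (75.5 to 86.4%) of 195 and 73.0% (70.0 to 75.8%) of 892, with median IP reads of 17 and 15. Every listed cluster at IgG 0 had at least 11 IP reads and so was at least 3.59-fold higher against 3 reads, which sets a lower end for the folds of loci with all clusters at IgG 0, and unlisted clusters of a locus were not analysed here.

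In 5 of the dense loci all minus clusters lay left of all plus clusters. The largest, on chromosome 17 at 27428706 to 27494676, held 31 clusters, 15 minus and 16 plus, with 718 IP and 127 IgG reads. Its ratio was 5.54, and 3.76 (3.20 to 4.44) when each IgG count listed as 0 was set to 3. The minus clusters ended at 27459905 and the plus clusters began at 27462775. The locus on chromosome 7 at 80922558 to 80974015 held 13 clusters, with 444 and 139 reads and a ratio of 2.67 (2.23 to 3.21) with zeros set to 3. On chromosome 9, 11 clusters at 67562959 to 67598538 held 162 IP reads and had IgG counts of 0. Against 3 reads per cluster this was at least 4.81-fold (interval 3.29 to 7.22), close to the lower end that the listing allows. The loci on chromosome 18 at 67212224 to 67233850 and on chromosome 6 at 127738908 to 127762425 had ratios of 3.96 (2.89 to 5.51) and 4.13 (2.48 to 7.21) with zeros set to 3. No dense locus had all plus clusters left of all minus clusters.

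**Figure D3:**
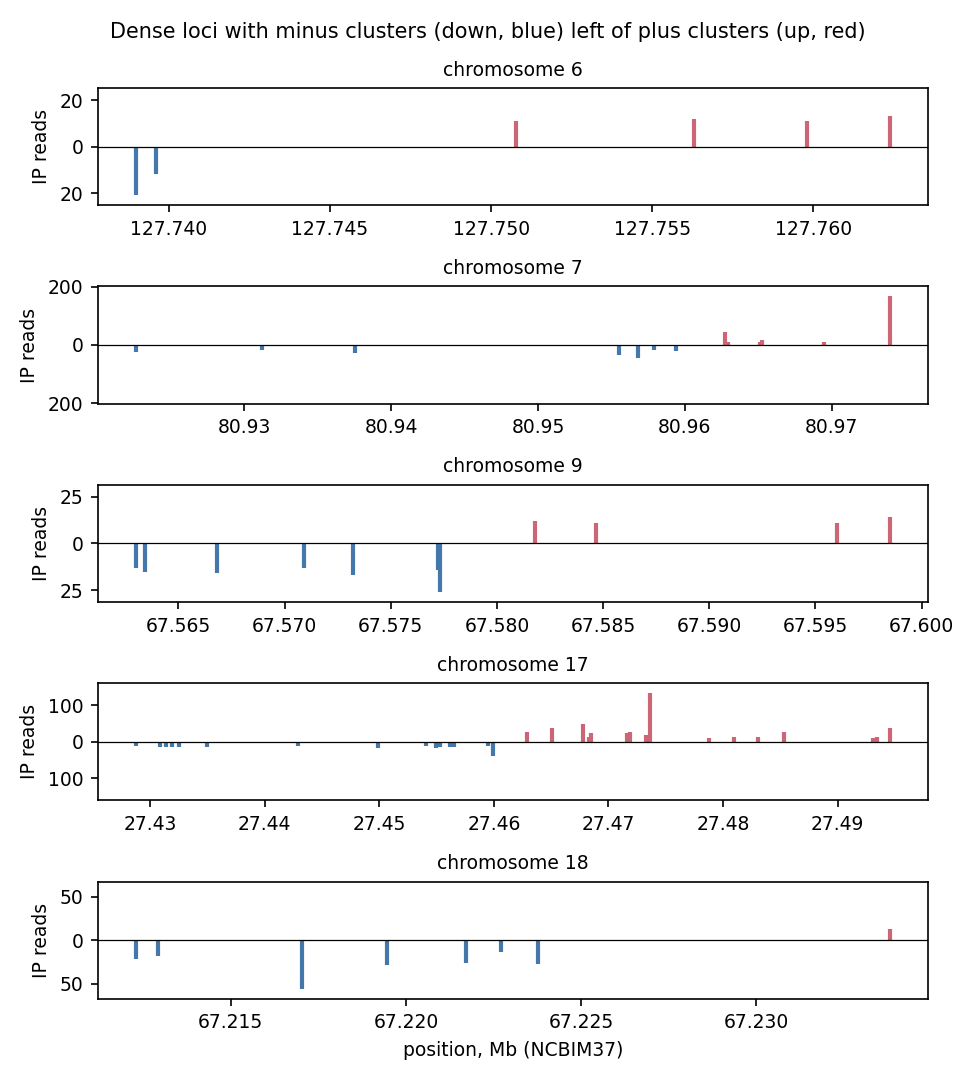
Each panel is 1 of the 5 dense loci with minus clusters left of plus clusters, with the NCBIM37 position in Mb on the horizontal axis and IP reads per cluster on the vertical axis. Red bars pointing up are plus clusters and blue bars pointing down are minus clusters; on chromosome 17 the 15 minus clusters end before the 16 plus clusters begin.

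Other low-read loci had clusters on 1 strand. On chromosome 2 at 92383056 to 92434686, 11 plus clusters held 180 IP and 20 IgG reads, a ratio of 4.30 (3.05 to 6.20) with zeros set to 3. On chromosome 4 at 93957499 to 93994906, 11 minus clusters held 248 and 30 reads, a ratio of 5.06 (3.70 to 7.05). The loci on chromosome 10 at 75302096 to 75322798, chromosome 14 at 45393751 to 45407726 and chromosome 15 at 74472359 to 74488523 had ratios of 4.51, 4.61 and 4.25. Clusters of so few reads were listed only at a high ratio, so ratios of about this size in these loci and in those with both strands were largely set by the listing.

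A stretch of 5.07 kb on chromosome 2 at 98502390 to 98507460 held 14 plus and 11 minus clusters, all at IgG 0. Together they had 2154 IP reads, 53.9% of them on the plus strand. They were at least 28.1-fold (interval 22.4 to 35.9) higher in the IP against 3 reads per cluster. The strands were mixed along this stretch, with 54.2% of neighbouring clusters on opposite strands. Near the start of chromosome 9, at 3000281 to 3036295, 39 clusters held 1168 IP reads and had IgG counts of 0, at least 9.78-fold (interval 8.08 to 11.9). There 97.0% of the IP reads were on the plus strand. Whether reads of these stretches also match other places in the genome was not checked.

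A repeated array on the minus strand of chromosome 8 at 126062680 to 126147646 held 55 clusters, of which neighbouring starts over 1000 bases apart were 1595 to 1771 bases apart. They held 1169823 IP and 920859 IgG reads, a ratio of 1.24 (1.24 to 1.25). Single clusters of the array ranged in ratio from 1.13 to 1.53. On chromosome 6 at 47605380 to 47635681, 8 minus clusters with a median length of 22 bases had 673 to 734 IP reads each and a summed ratio of 1.34 (1.28 to 1.39).

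The mitochondrial genome held 19 clusters. The 8 plus clusters had 16919 IP and 12699 IgG reads, a ratio of 1.31 of the sums, which 2 clusters dominated. The median ratio of the 7 plus clusters with IgG reads was 2.27. The largest, at 244 to 1004, had 13468 and 10148 reads and a ratio of 1.30 (1.27 to 1.33), and the next, at 1024 to 2670, had a ratio of 1.27 (1.20 to 1.34). The 11 minus clusters had 349 IP and 7 IgG reads, and 10 of them had an IgG count of 0. With these zeros set to 3 their summed ratio was 9.24, from clusters of few reads that were listed only at a high ratio. Ranked with the pseudocount of 1, the 4 highest ratios on this genome were minus clusters at IgG 0, from 49 IP reads at 12891 to 12944 (at least 16.005-fold) through 43 at 3027 to 3092 (at least 14.045-fold) and 29 at 6273 to 6594 (at least 9.47-fold) to 27 at 6639 to 6911 (at least 8.82-fold). The 1 minus cluster with IgG reads had a ratio of 12.2, above the last 2 of these lower bounds. The ratios of the plus clusters at 244 and at 1024 turned below 1 when scaled to the median ratio.

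On the Y chromosome 27 of the 31 clusters stood at a repeated spacing. The largest of the other 4, at 328067 to 328155 on the minus strand, had 10236 IP and 6374 IgG reads and a ratio of 1.57 (1.53 to 1.62). Over all chromosomes, 132 clusters of 14 to 19 bases lay at multiples of 524288 bases from another cluster of the same chromosome and strand, within 2 bases. Of these, 27 were on Y, 85 in the first 3000000 bases of other chromosomes and 20 elsewhere. The 111 of them that were plus clusters of 17 or 18 bases had 56.8 ± 7.09 IP reads (SD over clusters) and 22.3 ± 3.97 IgG reads, with a ratio of the sums of 2.49.

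**Figure D4:**
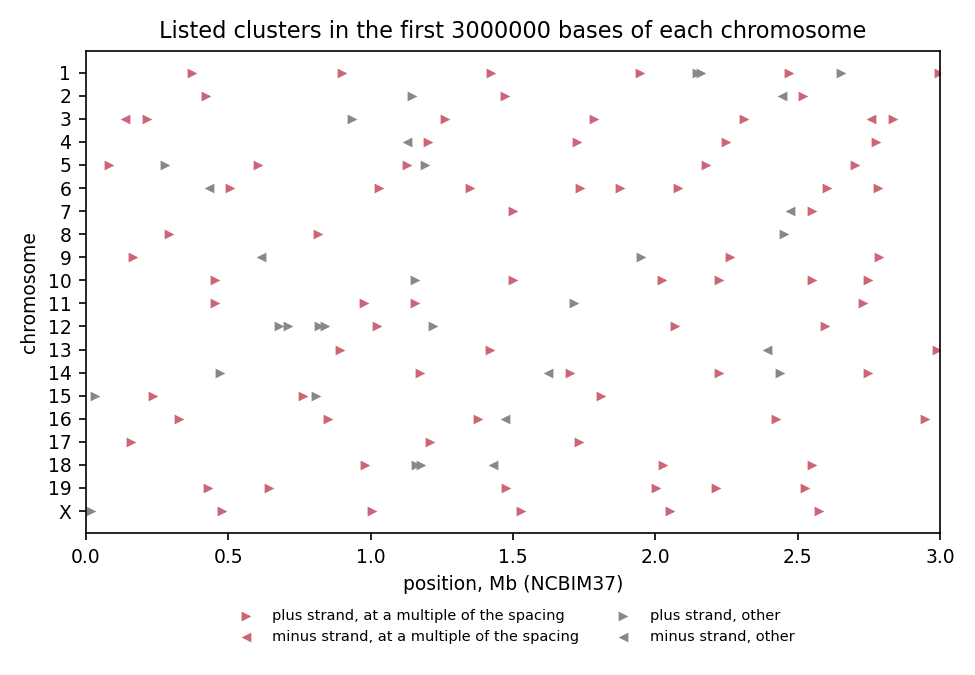
Each marker is a listed cluster in the first 3000000 bases of a chromosome other than Y and the mitochondrial genome, with the NCBIM37 position in Mb on the horizontal axis and the chromosome on the vertical axis; the direction of the triangle gives the strand. Of the 117 clusters, the 85 in red lie at a multiple of 524288 bases from another cluster of the same chromosome and strand.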

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

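The scaling per strand, zeros set to 3 and the removal of clusters by IgG count, length or spacing were chosen after the results were seen. With 1 library per group no replicate could be left out, and no paired analysis was possible because each group has 1 library. Alternatives for annotation classes, genes counted once and gene lists were not run. The number of clusters at a ratio of at least 2, 1690, stayed between 1569 and 1717 with other pseudocounts, no minimum, the authors' scaling, zeros set to 3 or without clusters at the repeated spacing. It fell to 1096 with the median scaling, 706 with at least 50 reads, 1025 at a ratio of at least 4, 843 without clusters at IgG 0 and 732 without clusters of 20 bases or shorter; the median scaling divides every ratio by 1.79, and the other 4 count fewer clusters or set a higher bar. Of 2117 clusters with IgG reads, the interval lay above 1 in 2083 and below 1 in 9. The split was 384 and 742 with the median scaling, which centres these same ratios on 1, and 2117 and 0 with the authors' scaling, under which the table was selected; both follow from how the values were chosen and do not test the direction. The count past the authors' p threshold fell from 2964 to 2375 with zeros set to 3 and to 2720 with 1 constant for both strands. All 244 lost then were plus clusters. Only clusters listed under the authors' scaling were recounted, so both counts could only fall. The single constant lowers every plus ratio and raises every minus ratio, so the loss on the plus strand follows from it.

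The share of clusters of 20 bases or shorter, 55.2%, was 53.03% in the upper part by IP reads, 6.24% weighted by IP reads and 53.1% without clusters at the repeated spacing. The minus share, 51.0%, became 60.1%, 77.4% and 53.2% under the same settings. The share at IgG 0, 28.6%, became 1.14% and 0.105% under the first 2 of these, since 810 of the 847 clusters at IgG 0 had under 50 IP reads. The clusters at the repeated spacing were 125 plus and 7 minus clusters, all of 14 to 19 bases. Their removal therefore lowers the share of short clusters and raises the minus share. The 3 largest clusters, all minus and longer than 20 bases, held 49.97% of the listed IP reads and so weigh on both read-weighted shares. The cause of the remaining shifts was not tested. The merging of overlaps changed nothing, since no clusters overlapped.

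With the median scaling, 18 log2 ratios turned below 0. They were -0.71, -0.68, -0.43, -0.76, -0.66, -0.57, -0.69, -0.11, -0.48 and -0.67 for the 10 largest clusters in order of IP reads. They were -0.46 and -0.50 for the mitochondrial clusters at 244 and 1024, -0.18 for the Y cluster at 328067, and -0.64, -0.42, -0.52, -0.49 and -0.43 for the dense loci starting at 115292265 on chromosome 5, 47605380 on 6, 126062680 on 8, 55797780 on 12 and 244 on the mitochondrial genome. With the authors' scaling in the authors' deposited table, the 5 lowest ratios turned to log2 values of 0.057, 0.064, 0.0689, 0.0690 and 0.0705. The cause was the scaling constant itself.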

Other observations

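All tests in this part were chosen after the pattern they test was seen, and no replicate exists for any of them.

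Over the 12 nuclear dense loci of at least 10 kb in which the clusters at IgG 0 were at least as many as the others, 5 had 1 strand only, 5 had all minus clusters left of all plus clusters, and 2 had mixed strands. Shuffling single clusters within each of the 13 dense loci with both strands gives 5 or more such loci with an exact probability of 8.97e-05. Clusters of 1 transcript share a strand, however, so single clusters are not independent. The left-right order alone, 5 of 5, has an exact two-sided sign test p of 0.0625. That is the smallest p this test can give with 5 loci, so it could not exclude chance order, which stays open. DNA carried into the IP would mix the strands. In the 12 nuclear loci 7.59% (Wilson interval 4.29 to 13.1%) of neighbouring clusters lay on opposite strands. The mitochondrial locus meets the same rule on span and IgG counts and had 61.1% (38.6 to 79.7%). With it the share was 13.5% (9.09 to 19.6%). With shorter loci added it was 19.1% (14.3 to 25.1%), among them the 5.07 kb stretch on chromosome 2 at 54.2%. These shares are the sorting itself seen another way, and DNA stays open. Transcription in both directions from 1 start, as known for some precursors of piRNAs, the small RNAs of germ cells, stays an untested hypothesis, since the finding that 0 loci had the opposite order was part of the pattern as seen, and the identity of the loci was not checked.

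The clusters spaced by 524288 bases were more than chance placement gave. There were 337 pairs at a multiple of the spacing, where the highest of 100 draws with moved positions had 4. The aligner named in the submitters' notes is known to fill unknown reference bases with pseudo-random ones, and short reads may match this filler in assembly gaps. The generator assumed here repeats its bases after 524288 steps when computed, but neither the generator in this version of the aligner nor the gap positions of the build were checked. Short clusters beside the spaced plus clusters, some of them among the 132, were paired across chromosomes on the same strand. Both members had the same offset to the spaced plus clusters in 196 of 849 pairs, where the highest of 100 random phases had 1. The offset could differ from pair to pair. Of the minus clusters beside the spaced plus clusters, 13 of 14 stood at 1 offset of 75044 bases, on 10 chromosomes.

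The IgG counts of 0 may be a record of low counts. Of the listed clusters, 0 had an IgG count of 1 to 3, although 50 had 4. The p threshold alone is argued against, since 258 clusters at IgG 0 had enough IP reads to pass it with 3 IgG reads, while the other 589 would be lost. Whether low counts were set to 0 or clusters with 1 to 3 IgG reads were left out stays open. A biological cause was not tested.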
